A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

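RNA was extracted with hot acid phenol from MATa (strain MP 384) and MATα-playing-a (strain LBHY29) cells grown in YPD with 0.1% BSA, with or without 10 nM α-factor for 2 h at 30 °C, in 3 biological replicates per group, and all 12 libraries were multiplexed in 1 lane, per the labels. The authors deposited 1 table per library with FPKM values of Cufflinks, its confidence bounds and gene coordinates for 7126 genes. The submitters' processing notes name CASAVA 1.8.2, TopHat 1.1.4 and Cufflinks 0.9.3 and give no genome build. No reads or alignments were used here.

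The files were checked for equal gene order, duplicates and zeros with Python 3.11.15 (pandas 2.3.3, numpy 2.4.6). In 81.8% of the values above 0 the upper confidence bound lay at FPKM plus 2 times its square root (variance ratio within 0.01 of 1). For these values the bounds say nothing of read numbers, and no bounds were used. Low values were also searched for a step of whole reads; no library showed one that stood clear of the same values blurred (strongest 3.61 against 2.87), so depth per library, and with it the counting error, is unknown. Of the gene IDs 6048 matched locus tags of the R64 reference, 1078 did not, and 12 of those matched had other coordinates there; 1420 genes overlap another listed gene. The reads' strand is not known and overlapping, antisense or paralogous genes were kept and named as uncertain.

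Samples were grouped by strain and treatment. Values entered as log2(FPKM + 1) as the authors scaled them, for the 6608 genes with a mean FPKM of at least 1. FPKM times gene length, summed per library, came to 5.02 to 6.225 times the total that the unit allows. The values thus carry a further scaling whose source is not known. Levels, filters and the constant added are in the units of the files. Summed FPKM was also lower in each stimulated library than in each unstimulated one. A single linear model of the 4 group means was fitted in limma 3.58.1 (R 4.3.3) with eBayes and an intensity trend. The 5 contrasts were the response of each strain, the strain difference (MATα-playing-a minus MATa) without and with α-factor, and the difference of the responses. Genes with a 2-sided Benjamini-Hochberg adjusted p below 0.05 over all tested genes were called. The model, contrasts, threshold, gene lists and rule for naming genes were fixed before the data were examined.

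Fixed lists of genes, written from general knowledge, were tested with camera (preset correlation 0.01), adjusted over the 34 lists with tested members: a-specific, α-specific, mating-type loci, haploid-specific, meiosis, pheromone-induced, pheromone pathway, cell fusion and polarity, karyogamy, filamentous growth, G1/S, histones, G2/M, M/G1, daughter separation, cell wall integrity, ribosomal proteins, ribosome biogenesis, general stress, heat shock, respiration, glycolysis, hexose transport, phosphate, iron, zinc, Gcn4 targets, methionine and sulfate, ergosterol, purine, selectable markers, galactose, seripauperins and structured RNAs. A list of mitochondrially encoded genes had 10 members in the files and none past the filter. Each call was repeated with a correlation estimated from the data and with fry. AFB1 had been placed in the a-specific list in error and was kept there, with the list also tested without it. AXL1 stood in both the a-specific and the haploid-specific list, and the a-specific list was not tested without AXL1. Members of each list were counted as higher, lower or not past the threshold, with p adjusted over all genes and over the list alone.

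Genes were named by rule: up to 8 per direction with the largest change among genes past the threshold with a mean of at least 10 FPKM in some group and, in pairwise comparisons, groups that do not overlap; up to 4 per list with the largest change; and all members of the mating-type lists. As the largest falls were of short genes at 0, up to 8 per direction that are above 0 in all libraries were added afterwards. Neighbours of mating-type genes and targets of Leu3 are named in the closing section. With groups of 3 against 3, non-overlapping values arise by chance in 10% of genes.

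Alternatives tried were pseudocounts of 0.1 and 10, no filter, a mean FPKM of at least 10, rescaling by median ratios, quantile normalisation, a fixed block, a fit to the compared libraries alone, no trend, a fold of at least 2, and each library left out in turn; genes under 200 nt left out and a block by culture were added later. Samples were also regrouped: all 10 splits of 3 against 3 for each pairwise comparison and 100 for the difference of responses. The procedure was tested on simulated data made from each gene's mean over all 12 libraries and its residual spread in the fitted model. In each of 5 runs 200 genes, drawn from those with a mean log2(FPKM + 1) of at least log2 of 10, were shifted in the stimulated MATa libraries. It recovered 94.0% of shifts of 1 on the log2 scale and 61.8% of shifts of 0.5, with 0.16% of unshifted genes called. A shifted list held 30 of the raised genes, each raised by a further 0.5 on the log2 scale. Camera called it in 5 of 5 runs and a random list in 0, at an unadjusted p below 0.05. As each member already had a raise of 0.5, 1 or 2, smaller shifts of lists were not tested. Values were drawn independently for each gene, so these runs do not test the preset correlation of camera. Figures were drawn with matplotlib 3.10.9. Count-based methods were not used, as the files hold no counts.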

Results

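The series holds RNA sequencing of 2 budding yeast strains, MATa and MATα-playing-a, each grown with and without the mating pheromone α-factor. There were 4 groups of 3 biological replicates, 12 libraries in all. Stimulated cultures had 10 nM α-factor for 2 h at 30 °C. Each library listed an FPKM value for 7126 genes, of which 487 were at 0 in all 12 libraries. The files carry no read counts and the depth of each library is unknown; the number of genes at 0 per library ran from 574 to 752. Libraries of the same group correlated at r = 0.955 to 0.980 (12 pairs on log2 values), and libraries of other groups at 0.849 to 0.972 (54 pairs). Ribosomal protein genes held 34.5% to 39.4% of the summed FPKM in unstimulated libraries and 29.2% to 30.4% in stimulated ones. Values are given as mean ± SD of 3 libraries in FPKM as scaled in the files, and a log2 change is given with its standard error. Coordinates are those of the files, counted from 1; they equalled the R64 reference for 6036 of the 6048 genes matched by name. The strand of the reads is not known, so genes that overlap another gene are named as such.

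In MATa cells α-factor raised the pheromone-induced genes, which had the highest median change of the fixed lists. FIG1, which codes for a membrane protein needed for mating, rose from 17.4 ± 5.32 to 10660 ± 789 FPKM (chromosome II, 316968 to 317864; log2 change 9.22 ± 0.17, limma adjusted p = 7.4e-12). PRM1, which acts in the fusion of mating cells, rose 84.6-fold, from 55.2 ± 7.45 to 4720 ± 62.0. FIG2, a cell wall adhesin of mating cells, rose 82.7-fold. FUS2, a fusion factor, rose 66.7-fold, from 20.9 ± 0.449 to 1459 ± 56.9 FPKM (adjusted p = 5.6e-14). PRM2 rose 60.7-fold. ASG7, an a-cell gene that acts on pheromone signalling after mating, rose 71.8-fold, from 112 ± 13.9 to 8127 ± 579 FPKM. Of the 32 genes of the fixed list of pheromone-induced genes, 30 rose, 1 fell and 1 did not pass, with a median log2 change of 3.13 (camera adjusted p = 7.7e-19). This list alone held in MATa cells with an estimated correlation (adjusted p = 0.00109). For called lists, counts of members adjusted over the list alone are given where they differed from those over all genes.

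Among genes that act later in mating, some rose and some fell in MATa cells. In the karyogamy list 7 of 13 genes rose and 5 fell (adjusted p = 0.0475, and 0.259 with an estimated correlation). PRM3, a protein of the nuclear envelope, rose 36.4-fold; CIK1, a partner of the kinesin Kar3, rose 22.3-fold; KAR4, a transcription factor of mating, rose from 505 ± 62.8 to 6795 ± 295 FPKM; KAR5 rose 7.85-fold. In the cell fusion and polarity list 10 of 19 genes rose and 5 fell (adjusted p = 0.0138, and 0.233 with an estimated correlation). In the pheromone pathway list 14 of 21 rose and 2 fell (adjusted p = 0.000728, and 0.167 with an estimated correlation). Among them, DIG2, a repressor of the mating transcription factor Ste12, rose 6.26-fold, the MAP kinase gene FUS3 rose 3.26-fold, and SST2, which turns the signal down, rose 4.17-fold. In the haploid-specific list 8 of 14 rose and 4 fell, and the list was not called (adjusted p = 0.182). FAR1, which arrests the cycle in response to pheromone, rose 2.65-fold and GPA1, the Gα subunit, 2.09-fold, while HO, the mating-type switch endonuclease, fell from 427 ± 29.2 to 58.0 ± 3.03 FPKM.

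Of the 9 genes of the a-specific list, 8 rose in MATa cells (median log2 change 1.17, adjusted p = 0.00145, and 0.167 with an estimated correlation). MFA1, an a-factor gene, rose from 7573 ± 1880 to 30810 ± 1644 FPKM, and MFA2, the other a-factor gene, from 7557 ± 316 to 17420 ± 3512. AGA2, the a-agglutinin subunit, rose from 1101 ± 93.0 to 8718 ± 1893, and STE2, the α-factor receptor, from 3674 ± 462 to 8241 ± 417. AXL1, STE6 and AFB1 rose by less, 1.36-fold, 1.21-fold and 1.54-fold. BAR1, the protease that degrades α-factor, was at 0 in all 6 MATa libraries. AFB1 stood in this list by mistake, as it is an α-cell gene; without it the median was 1.18 (adjusted p = 0.00258). Of the 4 α-specific genes none rose in MATa cells. MF(ALPHA)1 was at 7.96, 8.52 and 3.64 FPKM in the unstimulated MATa libraries and at 0 in the other 9 libraries, and passed as lower (adjusted p = 0.00737); the list was not called (adjusted p = 0.929; median 0.05, mean -0.49, tested direction up). Of the 6 mating-type locus genes 1 passed, HMRA1, up from 443 ± 28.9 to 579 ± 100 FPKM (adjusted p = 0.032), and 0 passed when adjusted over the list alone (list adjusted p = 0.415).

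Genes of the dividing cell fell in MATa cells. All 8 core histone genes fell (median log2 change -2.71, adjusted p = 1.5e-06, and 0.172 with an estimated correlation). HTB2, an H2B gene, fell from 4840 ± 208 to 204 ± 37.9 FPKM, and HTA2, an H2A gene, from 6291 ± 562 to 267 ± 12.2. Of the 31 G1/S genes 29 fell and 2 rose (median -1.14, adjusted p = 2.7e-08, and 0.202 with an estimated correlation). PCL1, a G1 cyclin, fell from 455 ± 51.3 to 11.1 ± 2.73 FPKM (log2 change -5.25 ± 0.22), and TOS4 and the cohesin gene MCD1 had log2 changes of -3.95 and -3.69. Of the 17 G2/M genes 14 fell and none rose, or 14 and 1 adjusted over the list alone (median -1.51, adjusted p = 0.000122, and 0.202 with an estimated correlation). HOF1, which acts in cytokinesis, fell from 138 ± 12.4 to 5.81 ± 0.687 FPKM, and the transcription factor gene SWI5 and the cyclin gene CLB1 had log2 changes of -3.71 and -3.75. Of the 16 M/G1 genes 11 fell and 3 rose (adjusted p = 0.036, and 0.302 with an estimated correlation), and of the 12 daughter separation genes 8 fell and 2 rose (adjusted p = 0.0169, and 0.395 with an estimated correlation). EGT2, a cell wall gene of daughter cells, fell from 1402 ± 174 to 48.1 ± 3.19 FPKM. Outside the lists, TOS6 fell from 1494 ± 285 FPKM to 51.4, 81.3 and 52.2 FPKM in the 3 stimulated libraries, and MRH1, a plasma membrane protein gene, from 5566 ± 1165 to 266 ± 56.8.

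Genes of protein synthesis fell in MATa cells. Of 138 ribosomal protein genes 137 fell, and all 138 adjusted over the list alone (median log2 change -0.64, adjusted p = 6.0e-17, and 0.279 with an estimated correlation). With quantile normalisation the median of this list was -0.13 (adjusted p = 0.0147). RPS21A showed the largest fall of them, 1.21 on the log2 scale; many genes of this list have a near-identical paralog, so that single values are uncertain. All 72 ribosome biogenesis genes fell (median -1.03, adjusted p = 3.1e-17, and 0.259 with an estimated correlation), with DBP2, an RNA helicase gene, down from 4396 ± 687 to 1054 ± 146 FPKM. Of 89 structured RNAs, snoRNAs and rRNAs among them, 45 fell and none rose, or 42 adjusted over the list alone (median -1.81, camera adjusted p = 0.000263, and 0.167 with an estimated correlation). The list holds 14 rRNA rows, 4 of them lower, which include identical, near-identical or overlapping entries and are not separate measurements. The 8 genes with the largest falls in MATa cells were all shorter than 200 nt and at 0 in all 3 stimulated libraries: snR39, snR54, snR128, snR66, snR51, YBR141W-A, YBR196C-B and YNR075C-A. snR39, a guide RNA of rRNA modification, was at 455, 290.0 and 341 FPKM unstimulated, and it overlaps another gene. Without read counts a listed 0 need not mean that an RNA was absent, so the size of these falls is uncertain. The structured RNA RPR1, for one, was at 0, 23.2 and 32.3 FPKM in the stimulated MATa libraries.

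Stress and cell wall genes rose in MATa cells. Of 34 general stress genes 33 rose and 1 fell (median log2 change 2.02, adjusted p = 1.6e-15, and 0.0985 with an estimated correlation); the small heat shock protein genes HSP42 and HSP26 rose 8.05-fold and 6.94-fold, and RTC3 rose 16.6-fold. TMA10, a ribosome-associated protein gene outside the lists, rose from 28.6 ± 10.5 to 1515 ± 235 FPKM. Of 24 heat shock genes 14 rose and 2 fell (adjusted p = 0.000766, and 0.325 with an estimated correlation). Of 25 cell wall integrity genes 18 rose and 4 fell, or 19 and 4 adjusted over the list alone (median 0.82, adjusted p = 0.000295, and 0.394 with an estimated correlation). GSC2, a glucan synthase gene, rose 13.1-fold and CHS1, a chitin synthase gene, 4.07-fold, while PIR1, a cell wall protein gene, fell from 4396 ± 421 to 610 ± 103 FPKM. Of 45 respiration genes 26 rose and 1 fell (adjusted p = 6.6e-06, and 0.395 with an estimated correlation), with CIT1, citrate synthase, up 4.79-fold. Of 16 meiosis genes 9 rose and 1 fell (adjusted p = 0.0372, and 0.259 with an estimated correlation). SPO11, the meiotic endonuclease gene, rose 11.9-fold, and IME4 rose 4.66-fold.

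Nutrient genes moved in both directions in MATa cells. Of 25 methionine and sulfate genes 23 rose and 1 fell (median log2 change 1.31, adjusted p = 4.4e-08, and 0.202 with an estimated correlation), STR3 by 5.64-fold and MET3 by 4.98-fold. Of 45 Gcn4 targets 21 rose and 12 fell (adjusted p = 0.05, and 0.325 with an estimated correlation), with ARG4 up 4.28-fold. Of 14 genes of the hexose transport list 8 rose and 3 fell (adjusted p = 0.0475, and 0.202 with an estimated correlation). HXT1, a low-affinity transporter, fell from 1873 ± 167 to 331 ± 31.2 FPKM and HXT9 rose 6.98-fold. Of 17 phosphate genes 13 fell and 4 rose (adjusted p = 0.0444, and 0.429 with an estimated correlation); the acid phosphatase genes PHO11 and PHO12, near-identical paralogs, had log2 changes of -2.81 and -2.85 while the transporter gene PHO89 rose 10.0-fold. Of 11 zinc genes 9 fell and none rose (adjusted p = 0.0138, and 0.395 with an estimated correlation), IZH1 most, by 1.87 on the log2 scale. The lists not called in MATa cells were iron (5 of 23 rose, 8 fell; adjusted p = 0.851), purine (8 of 16 rose, 6 fell; 0.689), ergosterol (8 of 25 rose, 8 fell; 0.826), glycolysis (3 of 18 rose, 5 fell, or 2 and 5 adjusted over the list alone; 0.936), galactose (1 of 7 rose, 1 fell, or 1 and 0 adjusted over the list alone; 0.911), filamentous growth (4 of 14 rose, 4 fell; 0.834), selectable markers (3 of 11 rose, 4 fell; 0.929) and seripauperins (4 of 28 rose, 6 fell; 0.784). The tested direction was opposite to the median or mean for galactose, ergosterol, filamentous growth and purine. With quantile normalisation the glycolysis list was called higher (median 0.25, camera adjusted p = 0.0132).

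Over all genes, 4403 of 6608 tested changed in MATa cells, 1885 higher and 2518 lower, with 646 and 499 of them by 2-fold or more; 4593 had an unadjusted p below 0.05. The median log2 change of all tested genes was -0.09, so that many small falls lie close to the shift of the whole distribution; after rescaling by median ratios 2175 were higher and 2158 lower.

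MATα-playing-a cells raised pheromone-induced genes as well. FIG1 rose from 12.3 ± 1.38 to 11120 ± 760 FPKM (log2 change 9.71 ± 0.17, adjusted p = 4.6e-12), PRM1 rose 100.4-fold, from 44.9 ± 3.20 to 4603 ± 24.3, FIG2 75.8-fold and FUS2 70.4-fold. AGA1, the anchor subunit of a-agglutinin, rose from 229 ± 33.8 to 10270 ± 1303 FPKM. KAR4 rose 17.9-fold and PRM3 42.7-fold. Of the 32 pheromone-induced genes 30 rose, 1 fell and 1 did not pass (median log2 change 3.18, adjusted p = 3.2e-17), and this was the 1 list that held in these cells with an estimated correlation (adjusted p = 0.00151). In the pheromone pathway list 12 of 21 rose and 3 fell (adjusted p = 0.00335, and 0.245 with an estimated correlation), and in the cell fusion and polarity list 9 of 19 rose and 8 fell (adjusted p = 0.0434, and 0.299 with an estimated correlation). The karyogamy list had 8 of 13 higher and 5 lower and was not called (adjusted p = 0.0618), nor was the haploid-specific list (6 of 14 higher, 4 lower; adjusted p = 0.33).

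In the a-specific list 5 of 9 genes rose and 1 fell in MATα-playing-a cells, and the list was not called (median log2 change 0.31, adjusted p = 0.251). STE2 rose 3.23-fold, from 565 ± 62.1 to 1822 ± 151 FPKM, MFA1 1.39-fold, STE6 1.24-fold and BAR1 1.78-fold, from 27.99 ± 0.183 to 50.7 ± 4.13 FPKM. AGA2 was at 0 in the 3 unstimulated libraries and at 20.0, 14.5 and 0 FPKM in the stimulated ones (adjusted p = 0.0125). AFB1 fell by 0.36 on the log2 scale, and ASG7, MFA2 and AXL1 did not pass (adjusted p = 0.161, 0.686 and 0.563). Among the α-specific genes SAG1, α-agglutinin, rose 3.82-fold, from 1366 ± 149 to 5217 ± 541 FPKM, while STE3, MF(ALPHA)1 and MF(ALPHA)2 were at 0 in all 6 libraries of this strain; the list was not called (adjusted p = 0.406; median 0.00, mean 0.48). The mating-type locus genes MATALPHA2, HMLALPHA2 and HMRA2 rose 3.86-fold, 3.86-fold and 4.10-fold (list adjusted p = 0.0183, and 0.254 with an estimated correlation). They are near-identical copies, so that the copy the reads came from is uncertain.

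Falls in MATα-playing-a cells followed the same groups. All 8 histone genes fell (median log2 change -2.45, adjusted p = 4.0e-06, and 0.245 with an estimated correlation), as did 28 of 31 G1/S genes with 2 higher (-1.32, adjusted p = 5.2e-08, and 0.254 with an estimated correlation), 14 of 17 G2/M genes (-1.59, adjusted p = 2.5e-05, and 0.245 with an estimated correlation) and 12 of 16 M/G1 genes with 2 higher (adjusted p = 0.0143, and 0.299 with an estimated correlation). EGT2 fell from 1519 ± 75.9 to 82.4 ± 6.79 FPKM, HOF1 from 154 ± 10.3 to 8.40 ± 1.72 and AIM20 from 501 ± 50.3 to 45.4 ± 11.2. Daughter separation genes were 3 higher and 7 lower of 12 and were not called (adjusted p = 0.0859). Of 138 ribosomal protein genes 127 fell, or 130 with 1 higher adjusted over the list alone (median -0.47, adjusted p = 9.3e-12, and 0.393 with an estimated correlation), a call that was lost with quantile normalisation (median -0.07, adjusted p = 0.348), and all 72 ribosome biogenesis genes fell (-1.001, adjusted p = 1.2e-16, and 0.299 with an estimated correlation). Of 89 structured RNAs 41 fell and 2 rose, or 35 and 2 adjusted over the list alone (-1.61, camera adjusted p = 0.00491, and 0.254 with an estimated correlation). Of these falls 11 were among 14 rRNA rows, which include identical, near-identical or overlapping entries and are not separate measurements. Of the 8 largest falls of all genes 5 were shorter than 200 nt and 6 were at 0 in all 3 stimulated libraries, snR66 and YBR196C-B most.

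General stress genes rose in MATα-playing-a cells, 33 of 34 (median log2 change 2.02, adjusted p = 1.2e-14, and 0.113 with an estimated correlation), with HSP26 up 9.17-fold and HSP12, a membrane stress protein gene, up 7.46-fold. Heat shock genes were 13 higher and 6 lower of 24 (adjusted p = 0.0143, and 0.449 with an estimated correlation), respiration genes 32 higher of 45 (adjusted p = 8.7e-07, and 0.415 with an estimated correlation), and cell wall integrity genes 19 higher and 4 lower of 25, or 20 and 4 adjusted over the list alone (median 1.06, adjusted p = 7.3e-05, and 0.393 with an estimated correlation). Meiosis genes were 9 higher and 3 lower of 16 (adjusted p = 0.0491, and 0.299 with an estimated correlation), SPO11 up 21.4-fold. Of 25 methionine and sulfate genes 21 rose, or 21 with 1 lower adjusted over the list alone (1.21, adjusted p = 2.3e-07, and 0.265 with an estimated correlation), STR3 by 8.04-fold. Gcn4 targets were 23 higher and 13 lower of 45 (adjusted p = 0.0491, and 0.38 with an estimated correlation), phosphate genes 4 higher and 13 lower of 17 (adjusted p = 0.0491, and 0.449 with an estimated correlation) and zinc genes 1 higher and 9 lower of 11 (adjusted p = 0.0183, and 0.449 with an estimated correlation). Not called were hexose transport (6 of 14 higher, 3 lower; adjusted p = 0.406), glycolysis (2 of 18 higher, 11 lower; 0.217), iron (5 of 23 higher, 7 lower; 0.974), purine (6 of 16 higher, 4 lower; 0.462), ergosterol (9 of 25 higher, 6 lower; 0.781), galactose (1 of 7 higher, 3 lower; 0.634), filamentous growth (4 of 14 higher, 6 lower; 0.693), selectable markers (4 of 11 higher, 5 lower; 0.812) and seripauperins (5 of 28 higher, 8 lower, or 4 and 6 adjusted over the list alone; 0.546). The tested direction was opposite to the median for ergosterol, filamentous growth and selectable markers. The glycolysis median went from -0.25 to 0.09 with quantile normalisation (camera adjusted p = 0.333 there).

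**Figure D1:**
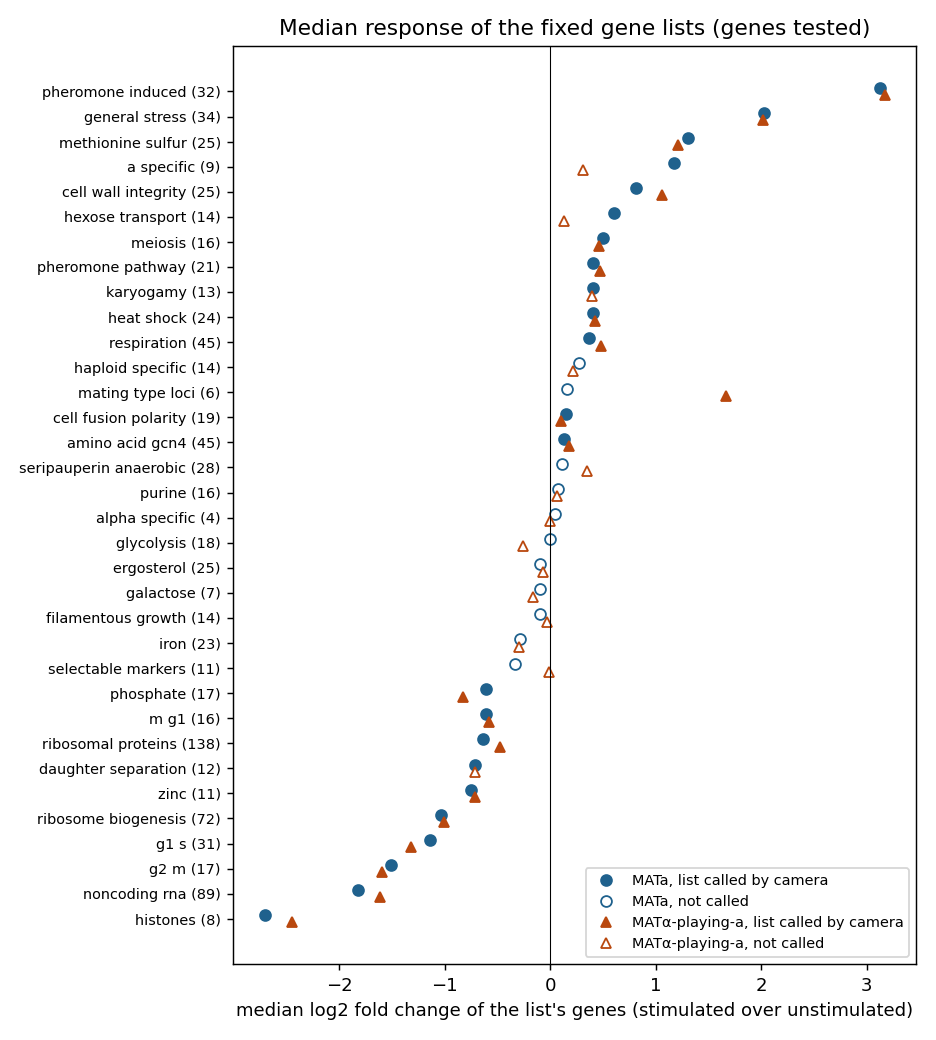
Median log2 fold change (stimulated over unstimulated, horizontal axis) of the fixed gene lists in MATa (circles) and MATα-playing-a cells (triangles); filled marks are lists called by camera at an adjusted p below 0.05. The pheromone-induced genes sit at 3.13 and 3.18 and the histone genes at -2.71 and -2.45.

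In all, 4554 of 6608 genes changed in MATα-playing-a cells, 1970 higher and 2584 lower, 738 and 499 of them by 2-fold or more, and 4715 had an unadjusted p below 0.05; after rescaling by median ratios 2266 were higher and 2206 lower. The log2 changes of the 2 strains correlated across genes at r = 0.866 (Spearman 0.902; 6608 genes, which are not independent). Of the genes higher in MATa cells, 1662 were also higher in MATα-playing-a cells, where 562 would be shared by chance; 2204 were lower in both (985 by chance), and 9 moved in opposite directions (1488 by chance).

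**Figure D2:**
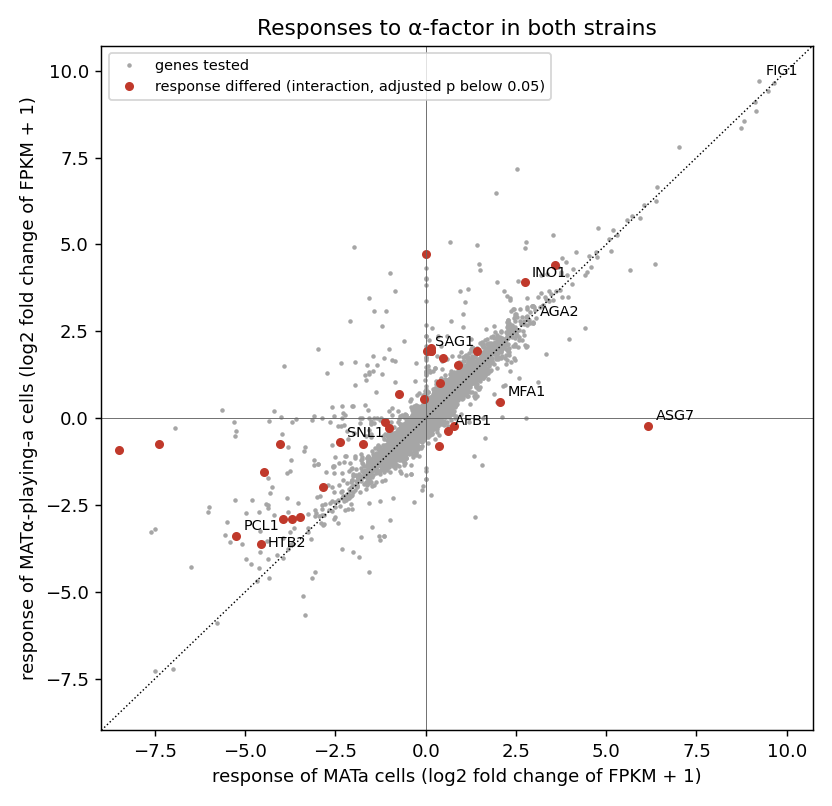
Log2 fold change of each tested gene (stimulated over unstimulated, FPKM + 1) in MATa cells (horizontal) and MATα-playing-a cells (vertical); the dotted line marks equal responses and red points are the 32 genes whose response differed. ASG7 lies far to the right, at 6.17 in MATa and -0.22 in MATα-playing-a cells.

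Without α-factor, genes of mating type were among those that differed between MATα-playing-a and MATa cells. AGA2 was at 1176, 1129 and 997 FPKM in MATa libraries and at 0 in all 3 unstimulated MATα-playing-a libraries (adjusted p = 4.4e-05). HMRA1, the a1 gene listed at the HMR cassette, was at 476, 433 and 421 FPKM in MATa libraries and at 0 in MATα-playing-a. The MAT locus is listed with its α genes, so a1 reads from the MAT locus of MATa cells would be counted under HMRA1. This difference may thus be that of mating type itself. The labels give no genotypes, so it is not known whether other genes at 0 in all libraries of 1 strain were altered there. These are BAR1, STE3, MF(ALPHA)1 and MF(ALPHA)2. Nor is it known for AGA2, which was above 0 in 2 stimulated libraries of MATα-playing-a. MFA2 was 7557 ± 316 in MATa and 167 ± 52.3 in MATα-playing-a cells (log2 difference -5.54 ± 0.21), STE6, the a-factor exporter, 521 ± 61.5 and 25.6 ± 3.59, STE2 3674 ± 462 and 565 ± 62.1, ASG7 112 ± 13.9 and 17.4 ± 1.57, and MFA1 7573 ± 1880 and 3313 ± 495. AXL1, the protease that processes a-factor, was lower by less (log2 difference -0.54 ± 0.08, limma adjusted p = 0.00727). It stands in the haploid-specific list as well, so it may not be an a-specific gene. BAR1 was at 0 in all MATa libraries and at 28.02, 27.8 and 28.2 FPKM in MATα-playing-a, and AFB1 was 10.3-fold higher there. In sum 7 of 9 genes of the a-specific list were lower and 2 higher (median -2.62, adjusted p = 1.0e-09), and the call held with an estimated correlation (adjusted p = 0.0156).

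Of the α-specific genes in unstimulated cells, SAG1 was higher in MATα-playing-a (1366 ± 149 against 110 ± 10.5 FPKM, 12.3-fold), while STE3, the a-factor receptor, was at 11.4, 8.40 and 12.2 FPKM in MATa libraries and at 0 in MATα-playing-a, and MF(ALPHA)2, an α-factor gene, at 78.1, 79.9 and 78.4 and at 0. MF(ALPHA)1 did not pass (adjusted p = 0.195), but did as lower when adjusted over the list alone, which gave 1 higher and 3 lower (list adjusted p = 0.0334, and 0.149 with an estimated correlation). STE3 overlaps another gene. MATALPHA1, the activator of α-specific genes, was at 0, 0 and 2.71 FPKM in MATa libraries and at 297, 255 and 307 in MATα-playing-a (adjusted p = 4.5e-05), and its copy HMLALPHA1 had almost the same values. MATALPHA2 and HMRA2 were 2.47-fold and 1.54-fold higher. Of 6 mating-type locus genes 5 were higher and 1 lower (median 1.31, camera adjusted p = 2.5e-06, and 0.0224 with an estimated correlation). Fry gave the list the other direction (fry adjusted p = 3.4e-05), so its direction depends on the test. Mating type is the difference that the design names between the strains, so a difference at these genes follows from the design. Several of the 6 are near-identical copies with like values, so they are not separate measurements. The p with the preset correlation therefore overstates the list.

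**Figure D3:**
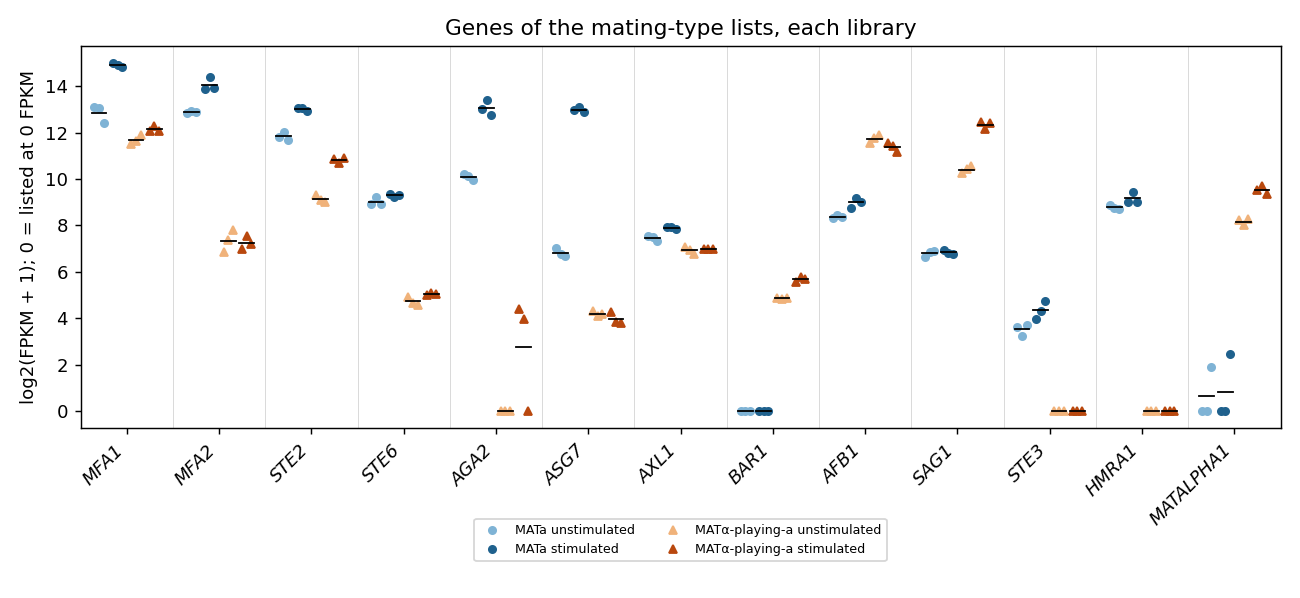
Each library's log2(FPKM + 1) for genes of the mating-type lists (vertical axis), 3 points per group with a bar at their mean on this scale; 0 is a gene listed at 0 FPKM. AGA2, STE3 and HMRA1 sit at 0 in unstimulated MATα-playing-a libraries and BAR1 in all MATa libraries.

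Genes outside the mating-type lists also differed between unstimulated strains. TRP1, a tryptophan synthesis gene often used as a marker, was 4314 ± 364 FPKM in MATα-playing-a and 208 ± 46.5 in MATa cells (20.9-fold; chromosome IV, 461842 to 462516), and YDR008C, which overlaps it, 19.0-fold higher. ADE2, an adenine synthesis gene, was 118 ± 12.2 against 307 ± 17.4 FPKM. Some genes of leucine and valine synthesis were lower in MATα-playing-a cells, with LEU1 at 374 ± 17.2 against 2070 ± 432 FPKM, OAC1, a mitochondrial carrier, 362 ± 20.3 against 1731 ± 168, and BAT1, a transaminase, 1463 ± 65.5 against 4777 ± 399 (log2 difference -1.70 ± 0.08). Yet of 45 Gcn4 targets only 4 were lower and 1 higher and the list was not called (adjusted p = 0.461). In the purine list 3 of 16 genes were lower, ADE2, ADE17 and ADE12 (the last 2 lost in all 6 models with 1 library left out), or 8 adjusted over the list alone (median -0.19, adjusted p = 2.5e-06, and 0.0619 with an estimated correlation). In the hexose transport list 2 of 14 genes were higher, HXT3 and HXT9, or 6 adjusted over the list alone (median 0.38, adjusted p = 1.1e-05), and the call held with an estimated correlation (adjusted p = 0.0156). Ribosomal protein genes were slightly lower as a list (median -0.17, 0 of 138 past the threshold in limma and 69 lower with 1 higher at an unadjusted p below 0.05, camera adjusted p = 1.0e-19, and 0.408 with an estimated correlation), and this call was lost with quantile normalisation (median -0.03, adjusted p = 0.0538).

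Further lists called between unstimulated strains rested on few genes. In the pheromone-induced list 4 of 32 genes were lower in MATα-playing-a cells, STE2, ASG7 and AGA1 among them, and 1 higher, BAR1, or 8 and 1 adjusted over the list alone (adjusted p = 0.00732, and 0.127 with an estimated correlation). The pheromone pathway had 2 of 21 lower, STE2 and STE3, or 3 adjusted over the list alone (adjusted p = 0.00187, and 0.127 with an estimated correlation). Of 23 iron genes 1 was lower, ISU2, or 2 adjusted over the list alone (median -0.27, adjusted p = 0.00064, and 0.618 with an estimated correlation), and of 17 G2/M genes none passed in limma, with 2 higher at an unadjusted p below 0.05 (median 0.15, adjusted p = 0.0101, and 0.463 with an estimated correlation). FUS1, a fusion gene, was lower (174 ± 20.4 against 111 ± 16.5 FPKM, adjusted p = 0.00911), 1 of 19 genes of the cell fusion and polarity list, or 1 higher and 3 lower adjusted over the list alone (list adjusted p = 0.519). YGP1, a cell wall glycoprotein gene, was lower too, by a log2 difference of -1.06 ± 0.12. In total 63 genes differed, 23 higher and 40 lower in MATα-playing-a cells, 14 and 19 of them by 2-fold or more; 825 had an unadjusted p below 0.05. The other lists were not called (adjusted p = 0.0787 for histones and 0.153 or more for the rest).

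With α-factor the a-specific genes differed between the strains as well. ASG7 was 8127 ± 579 FPKM in MATa and 14.9 ± 3.02 in MATα-playing-a cells (log2 difference -9.01 ± 0.13, adjusted p = 3.6e-12). MFA2 was 17420 ± 3512 and 152 ± 28.6, MFA1 30810 ± 1644 and 4573 ± 391, STE6 627 ± 28.7 and 31.9 ± 0.681, and STE2 8241 ± 417 and 1822 ± 151. AGA2 was at 8343, 10770 and 7040 FPKM in the MATa libraries. AXL1 was 240 ± 7.31 and 125 ± 0.820. Of the a-specific list 7 genes were lower and 2 higher (median -2.75, adjusted p = 1.1e-14), and the call held with an estimated correlation (adjusted p = 0.00535). Without AFB1 the medians were -2.66 unstimulated and -3.50 stimulated. The mating-type locus genes had 5 higher and 1 lower (median 3.09, adjusted p = 4.4e-10), and this held as well (adjusted p = 0.00657 with an estimated correlation), with MATALPHA2 at 1356 ± 138 against 158 ± 13.9 FPKM. Here too near-identical copies make the members of this list fewer separate measurements than genes, and a difference at them follows from the design. SAG1 was 45.2-fold higher, AFB1 5.22-fold and BAR1 at 46.4, 54.7 and 51.0 FPKM against 0. The α-specific list was 1 higher and 2 lower of 4 and was not called (adjusted p = 0.158).

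Some marker and amino acid genes differed in stimulated cells in the same direction as without α-factor. TRP1 was 40.3-fold higher in MATα-playing-a cells, ADE2 182 ± 10.9 against 684 ± 27.5 FPKM, LEU1 404 ± 46.1 against 1416 ± 274 and BAT1 1687 ± 34.0 against 3821 ± 378. GYP8, a GTPase-activating protein gene that lies beside STE2 (chromosome VI, 80419 to 81912), was 110 ± 13.8 against 456 ± 18.5. Of 45 Gcn4 targets 6 were lower and 1 higher, or 7 and 1 adjusted over the list alone (median -0.02, adjusted p = 0.0132, and 0.304 with an estimated correlation). Purine genes were 1 higher and 2 lower of 16, or 1 and 4 adjusted over the list alone (adjusted p = 0.000384, and 0.199 with an estimated correlation), with IMD2 the higher one. Selectable markers were 1 higher and 1 lower of 11, or 2 and 1 adjusted over the list alone (adjusted p = 0.189).

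Some genes of the cell cycle and the cell wall were higher in stimulated MATα-playing-a than in stimulated MATa cells. PCL1 was 40.5 ± 13.0 against 11.1 ± 2.73 FPKM, TOS4 45.9 ± 2.71 against 22.5 ± 2.24, MCD1 42.7 ± 3.07 against 23.6 ± 1.44 and YOX1, a repressor of M/G1 genes, 40.9 ± 4.65 against 21.0 ± 4.06. Of 31 G1/S genes 5 were higher, or 7 with 1 lower adjusted over the list alone (adjusted p = 0.00115, and 0.427 with an estimated correlation). Of 8 histone genes 3 were higher, HTA2, HTB2 and HHF1 (the last 2 lost in 5 of 6 models with 1 library left out), or 5 adjusted over the list alone (median 0.28, adjusted p = 1.3e-05, and 0.199 with an estimated correlation). The M/G1 list, with 2 of 16 genes higher, and the G2/M list, with 0 of 17 past limma's threshold and 1 higher at an unadjusted p below 0.05, were not called (medians -0.03 and 0.07, adjusted p = 0.68 and 0.409). Of 12 daughter separation genes 3 were higher, EGT2, DSE4 and NIS1 (adjusted p = 0.00115, and 0.349 with an estimated correlation). Of 25 cell wall integrity genes 4 were higher (median 0.18, adjusted p = 1.1e-05, and 0.349 with an estimated correlation): PST1 2716 ± 204 against 1190 ± 206 FPKM, PIR3 754 ± 18.0 against 379 ± 52.8, PIR1 and KDX1. Of 14 filamentous growth genes 2 were higher, CLN1 and SVS1, or 3 adjusted over the list alone (adjusted p = 0.0324, and 0.199 with an estimated correlation).

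Smaller shifts of whole lists between stimulated strains came with few or no genes past the threshold. Respiration genes were higher (median 0.14, 0 of 45 passed in limma, 6 higher and 1 lower at an unadjusted p below 0.05, camera adjusted p = 0.00267, and 0.681 with an estimated correlation). Glycolysis genes were lower (median -0.19, 0 of 18, or 6 adjusted over the list alone, with 6 lower and 1 higher unadjusted, adjusted p = 2.0e-06, and 0.304 with an estimated correlation), as were iron genes (median -0.23, 1 of 23, FET3; adjusted p = 0.00267, and 0.539 with an estimated correlation). The heat shock list was called lower (median -0.12, adjusted p = 0.0139, and 0.539 with an estimated correlation), although its 1 gene past the threshold, SSA4, was higher. The pheromone pathway had 3 of 21 lower, STE2, STE3 and the Gβ gene STE4 (adjusted p = 0.00994, and 0.199 with an estimated correlation). Structured RNAs were higher as a list (median 0.22, 1 of 89 passed, adjusted p = 0.0026, and 0.199 with an estimated correlation): snR39, at 0 in stimulated MATa libraries, was at 170, 147 and 231 FPKM in MATα-playing-a. The pheromone-induced genes were not called as a list (1 of 32 higher, 2 lower, adjusted p = 0.368). Ribosomal protein genes were not called either (0 of 138 in limma, with 1 higher unadjusted, median 0.00, adjusted p = 0.541), but were called higher with quantile normalisation (median 0.01, adjusted p = 0.0232).

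In total 146 genes differed between the stimulated strains, 103 higher and 43 lower in MATα-playing-a cells, 34 and 15 by 2-fold or more; 744 had an unadjusted p below 0.05. With quantile normalisation 90 were higher and 66 lower. The log2 strain differences with and without α-factor shared 18 higher and 21 lower genes, SAG1, TRP1 and BAR1 and AGA2, MFA2 and STE6 among them.

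Few genes passed the test for a different response to α-factor in the 2 strains. The simulation did not cover this comparison, so genes that did not pass may still differ. ASG7 rose 71.8-fold in MATa cells and did not rise in MATα-playing-a cells, a difference in log2 response of -6.39 ± 0.19 (adjusted p = 1.0e-08). MFA1 rose less in MATα-playing-a than in MATa cells (difference -1.58 ± 0.24). GYP8 and AFB1 rose in MATa and fell in MATα-playing-a cells (differences -1.01 ± 0.12 and -0.98 ± 0.17), as did YLR041W, which overlaps AFB1. MFA2, with -1.29 ± 0.30, did not pass (adjusted p = 0.124). Genes that rose more, or fell less, in MATα-playing-a cells were SAG1 (1.88 ± 0.15), HMRA2 (1.87 ± 0.16), MATALPHA2 (1.79 ± 0.16), PST1 (1.27 ± 0.21), SPO11 (0.85 ± 0.15) and SNL1 (1.68 ± 0.14), a chaperone regulator gene beside BAR1 that fell from 624 ± 13.1 to 121 ± 15.4 FPKM in MATa and from 652 ± 40.8 to 407 ± 47.1 in MATα-playing-a cells. Some cell cycle genes fell less in MATα-playing-a cells, among them PCL1 (1.87 ± 0.32, adjusted p = 0.0272), TOS4 (1.05 ± 0.14, adjusted p = 0.00511), MCD1 (0.78 ± 0.11), HTA2 (0.92 ± 0.13) and PCL9 (0.65 ± 0.11). In all 32 genes differed in response, 27 higher and 5 lower, 16 and 4 by 2-fold or more; 771 had an unadjusted p below 0.05. The largest differences upward were of short genes at 0 in stimulated MATa libraries, snR39 and YBR141W-A, which overlap other genes. Without read counts a listed 0 leaves the size of these differences uncertain.

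**Figure D4:**
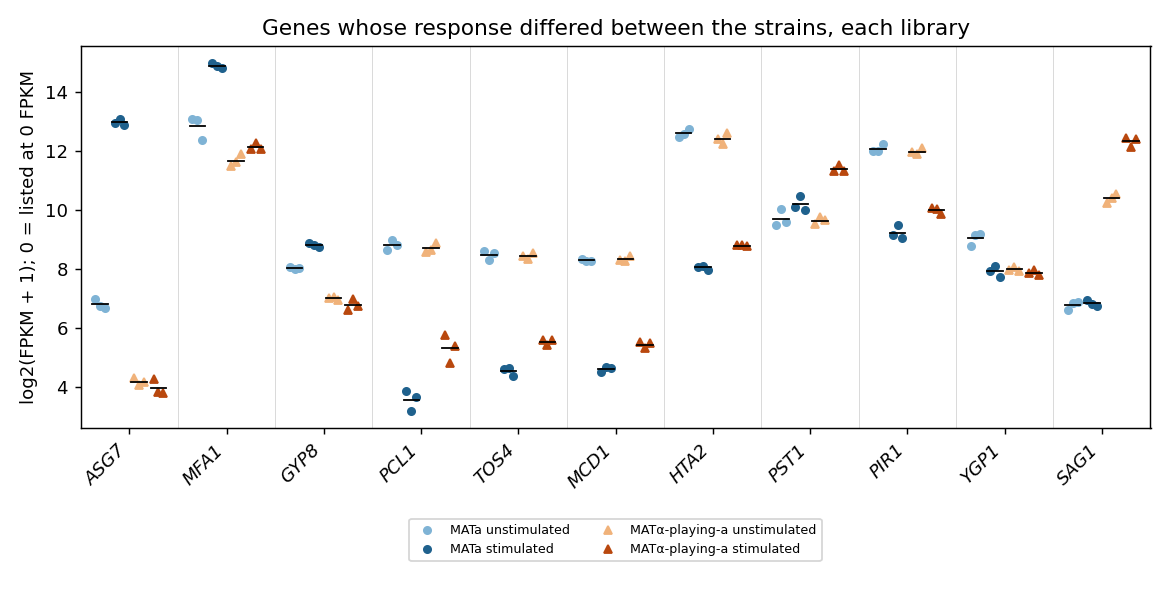
Each library's log2(FPKM + 1) for 11 genes whose response differed (vertical axis), 3 points per group with a bar at their mean on this scale. ASG7 rises in MATa libraries alone and SAG1 in MATα-playing-a libraries alone, while PCL1, TOS4 and MCD1 fall further in MATa libraries.

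Of the lists, a-specific genes had a lower change with α-factor in MATα-playing-a than in MATa cells (median difference -0.39, or -0.75 with quantile normalisation and -0.29 without AFB1, 3 of 9 lower, or 1 higher and 5 lower adjusted over the list alone; adjusted p = 0.000106, and 0.0929 with an estimated correlation) and mating-type locus genes a higher one (1.54, 3 of 6, adjusted p = 1.4e-05, and 0.0517 with an estimated correlation). The mating-type locus list holds near-identical copies, so its members are not separate measurements. Genes of the hexose transport list had a lower change with α-factor in MATα-playing-a than in MATa cells (median -0.45, 0 of 14 in limma, or 6 adjusted over the list alone and 9 lower unadjusted, adjusted p = 4.3e-06), the 1 call that held with an estimated correlation (adjusted p = 0.0198). HXT3 fell from 4970 ± 390 to 2856 ± 62.3 FPKM in MATα-playing-a and from 3554 ± 263 to 2846 ± 49.7 in MATa cells. Histone genes fell less in MATα-playing-a cells (0.40, 1 of 8, or 6 adjusted over the list alone; adjusted p = 1.1e-05, and 0.308 with an estimated correlation), as did ribosomal protein genes (0.19, 0 of 138, with 28 higher unadjusted, adjusted p = 4.2e-09, and 0.8 with an estimated correlation), with medians of 0.21 and 0.05 under quantile normalisation. Glycolysis genes were shifted down (-0.23, 0 of 18, with 5 lower unadjusted, adjusted p = 3.8e-05, and 0.701 with an estimated correlation) and cell wall integrity genes up (0.09, 2 of 25, PST1 and PIR1, or 3 adjusted over the list alone; adjusted p = 0.025, and 0.977 with an estimated correlation). The G1/S list was not called (median 0.05, 3 of 31, or 4 adjusted over the list alone; adjusted p = 0.274), nor was G2/M (-0.08, adjusted p = 0.381) or the pheromone-induced list (0.08, 1 of 32, ASG7, or 1 higher and 1 lower adjusted over the list alone; adjusted p = 0.359), and the other lists had an adjusted p of 0.087 or more. The G2/M list was called lower with quantile normalisation (median -0.17, camera adjusted p = 0.0433).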

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

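The tests of neighbouring genes, structured RNAs and G1/S genes in this part were chosen after the results were seen.

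The strains differed in their response to α-factor at 32 genes, by the tested difference of the 2 responses, and the genes and lists of this part are given for that reason. With a block by culture 15 genes passed, 14 of them among these 32. Among 100 splits of the libraries 4 gave as many, the real one included, a share under 0.05, and the highest other split gave 58 genes. The next gave 43 and 38; these 3 splits keep the strains whole among the stimulated libraries and exchange 1 library between the strains among the unstimulated ones. They therefore measure mostly the strain difference of stimulated cells, which is a structure of the samples. Exchanging libraries between the strains also breaks up the strain differences themselves. The share therefore does not decide whether the responses differ. For the other comparisons the 10 splits of 3 against 3 are too few for a share under 0.05: the MATa response had 4403 genes against 1 in the highest other split, the MATα-playing-a response 4554 against 2, the unstimulated strains 63 against 10 and the stimulated strains 146 against 2.

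Mating-type genes had large differences of response: ASG7 -6.39, MFA1 -1.58, AFB1 -0.98 with the overlapping YLR041W -1.18, SAG1 1.88, and the near-identical MATALPHA2 and HMLALPHA2 (1.79 each) and HMRA2 (1.87). The a-specific list had a median of -0.39 (-0.75 with quantile normalisation and -0.29 without AFB1) and the mating-type loci 1.54. Mating type is the difference that the design names between the strains. Cell wall and stress genes were PST1 1.27, PIR1 0.87 and YGP1 1.01, with a median of 0.09 for the cell wall integrity list. Genes of the cycle and of daughter cells were HTA2 0.92, PCL9 0.65, SVS1 0.71 and NIS1 0.60, with 0.40 for the histone list. SPO11 differed by 0.85 and YDR008C, which overlaps TRP1, by 1.44. YFL012W (3.29), YGL118C (4.71) and YKR040C (2.94) were at 0 in all stimulated MATa libraries and below 40 FPKM in the others, so the size of these differences depends on the constant added to FPKM. The 5 genes outside the naming rule, named after their values were seen, were APL1 (0.60), ARI1 (0.51), HEM25 (0.62), INO1 (1.16) and DIC1 (0.98). The other lists had medians of 0.19 (ribosomal proteins), -0.23 (glycolysis) and -0.45 (hexose transport).

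Genes beside a-specific and α-specific genes differed between the strains: 7 of the 26 neighbours of 13 such genes passed in some comparison of the strains, namely SNL1 beside BAR1 (difference of responses 1.68), GYP8 (-1.01) and BST1 beside STE2, MRX12 and APL1 beside SAG1, THI22 beside AXL1, and YLR041W over AFB1. Chance placement is argued against, as 10000 random gene sets of the same size held 0.592 called genes on average and 5 at most. Reads of the mating-type gene counted in its neighbour are argued against for 2 genes that moved the opposite way, MRX12 (-0.67 in stimulated cells, adjusted p = 0.000821, beside the higher SAG1) and BST1 (0.36, adjusted p = 0.0254, beside the lower STE2), and as the whole cause for SNL1, whose stimulated strain difference of 285.9 FPKM lay above all of BAR1 (50.7), and GYP8, which changed by -18.46 FPKM (standard error 8.24, adjusted p = 0.0265) in MATα-playing-a cells, where STE2 rose. For the 3 others that moved the same way, APL1, THI22 and YLR041W, such reads cannot be told apart from a change of the gene, since strand and read positions are not known. Transcription of one gene acting on the next, or an edited locus in one strain, may be the source and stays untested, as the labels give no genotype.

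Structured RNAs were lower after α-factor in both strains (medians -1.81 and -1.61), and among short genes snR39 (7.57) and YBR141W-A (6.63) also differed in response, being at 0 in stimulated MATa libraries. Without read counts a listed 0 of a short gene need not mean absence, so these 2 differences are uncertain. Short length and low level are argued against as the whole cause: genes matched for both had medians of -0.0302 in MATa (10000 draws, -0.293 to 0.0843) and -0.0034 in MATα-playing-a cells (-0.173 to 0.199). Of the 14 RNAs of 300 nt or more that are not rRNA, 12 were lower in MATa cells, and 9 were lower and 1 higher (snR42, 0.84) in MATα-playing-a cells, with TLC1, the telomerase RNA, at -2.31 in MATa. Carry-over of RNA without poly(A) tails cannot be told apart from a change in the cell, as rRNAs differed from the other structured RNAs by 0.9629 in MATa and by -0.9922 in MATα-playing-a cells, within their spread (interquartile range 3.18 and 2.47). A lower output of these RNAs in arrested cells is a candidate explanation, as is a different selection of RNA in the stimulated preparations, which coincides with treatment.

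The G1/S genes PCL1 (1.87), TOS4 (1.05) and MCD1 (0.78) fell less in MATα-playing-a cells. A small share of cells still dividing would leave G1/S and G2/M genes at a like share of their level. In 8 of 31 G1/S genes the stimulated level lay above that of MATa cells by a median of 6.74% (5.26% to 9.54%). In 6 of 17 G2/M genes it did so by 1.608% (-1.11% to 2.50%, bootstrap over genes). Both are shares of the step from stimulated MATa to unstimulated MATα-playing-a cells, for genes at least 4-fold lower after α-factor in MATa cells. With members at least 2-fold lower the medians were 5.40% in 21 genes (3.57% to 6.32%) and 1.608% in 10 (-1.11% to 2.50%). The medians differed between the lists, but the G1/S members include PCL1, TOS4 and MCD1, and the bootstrap draws genes, not cultures. A dividing share is therefore not decided. Dependence on 1 library is argued against for TOS4 and MCD1, which passed in 12 of 12 models with 1 library left out, and stays open for PCL1, which passed in 5 and did not without unstimulated MATa replicate 2 (1.79) or 3 (1.86), stimulated MATa replicate 3 (1.91), unstimulated MATα-playing-a replicate 1 (1.81), 2 (1.83) or 3 (1.96), or stimulated MATα-playing-a replicate 3 (1.84). Scaling is argued against for TOS4 and MCD1, which passed with median ratios and quantile normalisation (lowest difference 0.6361), and stays open for PCL1, whose difference went from 1.87 ± 0.32 to 1.51 ± 0.32 with quantile normalisation (adjusted p = 0.0876, and 0.0263 with median ratios), a smaller difference with the same error. Whether an incomplete arrest left G1/S genes higher is not settled by the shares given above.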

How the results depend on the processing

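The culture block and the models without genes under 200 nt, and the lists without AFB1 or with quantile values, were added after the results were seen. The total counts of the 5 comparisons stayed within 1.5 times under pseudocounts, filters, rescaling, the fixed block and no trend; between stimulated strains the lower genes went from 43 to 66 with quantile normalisation. A fold of at least 2 left 1145, 1237, 33, 49 and 20 genes in the 5 comparisons, by its construction. A model of the compared libraries alone gave 33 genes between unstimulated strains; it has fewer libraries. With 1 library left out, the MATa response had 4115 to 4280 genes, the MATα-playing-a response 4210 to 4354, the unstimulated strains 46 to 55, the stimulated strains 85 to 138 (85 without stimulated MATa replicate 1 and 96 without stimulated MATα-playing-a replicate 1 or 3) and the difference of responses 21 to 46 (21 without unstimulated MATα-playing-a replicate 2). The correlation of the responses was 0.780 with a pseudocount of 0.1 and 0.934 with 10. With an estimated correlation camera called 1, 1, 3, 2 and 1 lists, in place of 23, 20, 10, 15 and 7, and fry called 31 in MATα-playing-a cells. Fry gave the mating-type loci the other direction between unstimulated strains (adjusted p = 3.4e-05, median 1.31), and TPI1 went from -0.35 to 0.12 in MATa cells with quantile normalisation; the cause was not tested. Median ratios ended 3 list calls in MATa (meiosis, karyogamy, hexose transport) and 2 in MATα-playing-a cells (meiosis, cell fusion and polarity). A block by replicate number ended 2 (karyogamy, Gcn4 targets), 3 (meiosis, cell fusion and polarity, Gcn4 targets) and, between unstimulated strains, 1 (α-specific), and added 1 between stimulated strains (hexose transport). Quantile normalisation ended 2 list calls in MATa (hexose transport, meiosis), 4 in MATα-playing-a cells (Gcn4 targets, cell fusion and polarity, meiosis, ribosomal proteins), 2 between unstimulated strains (α-specific, ribosomal proteins), 1 between stimulated strains (filamentous growth) and 1 for the difference of responses (cell wall integrity). It added 1 call in MATa (glycolysis) and 0 in MATα-playing-a cells. Between unstimulated strains it added 6 (cell wall integrity, ergosterol, glycolysis, M/G1, respiration, ribosome biogenesis). Between stimulated strains it added 3 (galactose, hexose transport, ribosomal proteins), and for the difference of responses 2 (Gcn4 targets, G2/M). For the difference of responses a block by culture gave 15 genes, against 32 in the main model, so this count fell outside 1.5 times. Of the 15 genes, 14 were called in the main model too. A block by replicate number gave 25. Residuals gave no sign that the numbers pair the cultures: those of the same number correlated at -0.28 to 0.27, and 2 of 12 libraries matched their own number best. With 3 libraries per group such correlations vary widely, so whether the numbers pair the cultures is not known. Of the named calls 8 of 137, 10 of 139, 10 of 39, 13 of 59 and 13 of 27 were lost in some setting. With 1 library left out, calls between unstimulated strains were lost in 6 of 6 models for ADE12 and ADE17, 5 for KDX1, 4 for ARG3, HMRA2, HXT9 and ILV3, and 3 for AGA1, NFG1 and YCR041W. Between stimulated strains they were lost in 6 for ILV3 and SSA3, 5 for DSE4, FET3, HHF1, HTB2, MET8, PHO11 and PHO12, 4 for CLN1, SHM2 and YOX1, and 2 for HIS4. In MATa cells they were lost in 5 for GAL2 and HMRA1, 4 for STE6, and 3 for FIT3 and PAU20, and in MATα-playing-a cells in 4 for BAR1, 3 for AFB1 and MFA1, and 2 for AGA2, STE6, snR8 and snR190. Calls of the difference of responses were lost in 11 of 12 models for PIR1, 10 for SVS1, YDR008C and YGL118C, 9 for AFB1, NIS1, PCL9 and SPO11, 8 for YGP1, 7 for PCL1 and 5 for PST1. Depth is unknown, so what it limits cannot be given.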

Other observations

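The test of leucine genes and the choice of retrotransposon genes in this part were made after the results were seen.

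Most tested genes of the Ty2, Ty3, Ty4 and Ty5 retrotransposon families rose after α-factor in both strains, while most Ty1 genes did not pass; the families were not tested as lists. The 3 tested genes of the Ty5 element on chromosome III were at 0 in all 6 unstimulated libraries, and YCL074W was at 552, 523 and 611 FPKM in stimulated MATa and at 494, 386 and 496 in stimulated MATα-playing-a libraries. In the Ty3 family 4 of 5 genes rose in each strain, with medians of 4.41 and 4.12. YGR109W-B rose from 71.7 ± 3.63 to 1969 ± 223 FPKM in MATa and from 72.2 ± 3.20 to 1831 ± 362 in MATα-playing-a cells. All 4 tested Ty4 genes rose (1.83 and 1.495), as did 18 of 20 Ty2 genes (1.31 and 1.18). Of 41 Ty1 genes 13 rose and 1 fell in MATa (0.43), and 15 rose and 4 fell in MATα-playing-a cells (0.36), where 1885 and 1970 of all 6608 tested genes rose. The medians had the same sign with median ratios and with quantile normalisation, the smallest being 0.12 for Ty1 in MATα-playing-a cells with the latter. No Ty gene passed limma's test of the difference of responses, with 4 Ty1 genes at an unadjusted p below 0.05. Copies within a family can be near identical, and 8 of the 12 tested Ty3, Ty4 and Ty5 genes overlap another listed gene, so the copy a read came from is uncertain in the families with more than 1 element.

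Some genes under Leu3, the regulator of leucine synthesis, were lower in MATα-playing-a cells: 6 of 9 tested targets, a set written after the results were seen and not tested as a list, passed as lower in some condition, LEU1, ILV2, BAT1, OAC1, GDH1 and BAP2, with medians of -1.31 unstimulated and -0.87 stimulated (-1.20 and -1.004 with quantile normalisation). A lower amino acid programme as a whole is argued against, since the 40 Gcn4 targets that are not Leu3 targets had a median strain difference of 0.0134 unstimulated (SD 0.231) and 0.0091 stimulated. The 6 targets were kept because they passed, so their low medians follow from that choice and are no support for lower Leu3 activity. Lower activity of Leu3 may be the source, as an untested hypothesis. The 3 targets that did not pass had a median of -0.2328 unstimulated and -0.1546 stimulated, but LEU2 among them was higher (0.30 and 0.94), so 3 genes are too few to decide. The labels give no genotype, so a LEU2 marker in one strain stays open.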
